A study of Macaca mulatta with 45 samples.

How the data were processed

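Total RNA was extracted from 3 brain regions of 15 rhesus macaques, and 1 library was made per animal and region. Per the labels, tissue was homogenised after perfusion with saline, and libraries were made with a stranded total RNA kit after removal of ribosomal RNA. The authors deposited 1 table of raw read counts per gene for the 45 libraries, which was the only file used here. The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2 without versions; the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited counts were whole numbers with different totals per library, from 6625435 to 12541507, so they had not been scaled. Where strand was not used in counting, reads of overlapping antisense genes cannot be told apart, and reads of near-identical copies, such as MHC and haemoglobin genes, could be split among them.

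The table held 30246 Ensembl gene IDs, and all 45 columns were matched to a library by their labels. Symbols were taken from a table of gene names by ID, and 15769 IDs had one. Of 15288 IDs with a mean of at least 10 counts, 11416 had a symbol; IDs without one held 16 to 23.8% of the counts of a library. No coordinates are given, because the build is not named.

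The group of each library, the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for the alternatives stated in the closing section to have been added afterwards. Each irradiation comparison was fitted within 1 region on its 15 libraries of 3 groups, with TMM scaling, edgeR's default filter on low counts, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). Regions were compared within the 5 control animals with animal as a block, and differences of the irradiation effect between regions were tested on all 45 libraries with animal as a block. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and all tests were two-sided. The animals were separate within a group and shared between regions. Libraries of the same animal in different regions deviated together from their group means (median r = 0.31 over 45 pairs, across genes, 41 of them above 0.1), which is the pairing that the animal block uses; it comes from the labels. Log2 CPM was computed with a prior count of 2.

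Of 37 gene lists of cell types and pathways, 32 had at least 5 tested members and entered 288 list tests over 9 irradiation comparisons. A list was tested with fry (limma 3.58.1), which asks whether its genes move, on balance, in 1 direction, without comparing them with other genes. The alternative was camera, which compares a list with all other genes, with a preset correlation of 0.01 or an estimated correlation. It asks a different question, and adjusted p-values given below with an estimated correlation are from camera. Adjusted p-values of lists were taken over all list tests. Of the 89 list tests that fry called, 31 were also called by camera with an estimated correlation.

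Genes were named by a fixed rule. For irradiation against control these were the 8 largest rises and the 8 largest falls among genes past the threshold with a symbol, a mean of at least 1 CPM and every irradiated library on the same side of the control mean, and up to 3 members past the threshold from each list. For a described list with none past it, the first 2 tested members are given as values only; where fewer than 5 genes passed, the 5 smallest p-values are given as values only. In other comparisons the 5 largest rises and 5 largest falls were taken, with the first 2 tested members of cell type lists for region comparisons. Genes named elsewhere, such as those shared by regions, were chosen after their values were seen. Some genes that the rule names are not reported here.

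The steps were tested on simulated data with 200 changed genes and the real library sizes. For fWBI against control, 4-fold changes were recovered in 87.9% of genes in white matter, 97% in hippocampus and 92.4% in prefrontal cortex, and 2-fold changes in 67.2, 74.6 and 76.1%. For TBI against control, 2-fold changes were recovered in 61.2, 70.1 and 68.7% in the same order, so smaller changes could be missed at this depth and group size. No pair of libraries agreed within sampling noise: the smallest chi-square per gene between libraries of 1 group was 6.94.

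The alternatives were DESeq2's size factors in place of TMM, the DESeq2 test (1.42.0), limma-voom with quality weights, other filters on low counts, a log2 fold minimum of 1, other sets of libraries in the fit, a covariate for the grey or white matter share of the dissection, the animal number as a block, and leaving out each animal in turn. The share of grey or white matter was not measured. Its covariate was a mean log2 CPM from the same libraries, of the pan-neuronal list in white matter and of the oligodendrocyte and myelin list elsewhere. Shared fold changes of fWBI and TBI were set against 20 simulated data sets per region and against splits of the controls. Ages, sexes and sequencing batches were not used here, so group differences may include theirs.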

Results

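Gene expression was measured by total RNA sequencing in 3 regions of the rhesus macaque brain. These were the hippocampus, the prefrontal cortex of Brodmann area 46, and the deep white matter of the centrum semiovale. The 15 animals formed 3 groups of 5. Control animals had received 10 Gy to the thorax only, with a labelled brain dose of 0.1 Gy as an upper estimate. The fWBI animals had received fractionated whole-brain irradiation, 40 Gy given as 8 fractions of 5 Gy, 12 months before necropsy. The TBI animals had received total body irradiation as 1 dose of 6.75 to 8.05 Gy, 6 to 9 years before necropsy. Each animal gave 1 library per region, so the 45 libraries fell into 9 groups of 5. Total counts ranged from 6625435 to 12541507 per library. The comparisons asked how each kind of irradiation differed from control in each region, how the irradiation groups differed from each other, and whether the effects differed between regions. Fold changes are on the log2 scale with their standard error (SE), n = 5 animals per group, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Every gene given below with a value as having risen or fallen between animal groups in 1 region lay on that side of the other group's mean in 5 of 5 animals. Dose, time since exposure and the way the dose was given all differed between the fWBI and TBI groups, so a difference between them belongs to none of these alone.

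The 3 regions of the control animals differed as dissections of white and grey matter do. Against prefrontal cortex, white matter was higher in the myelin genes MBP (4.92 ± 0.49, adjusted p = 1.63e-05) and MOBP (5.25 ± 0.51, adjusted p = 1.47e-05). All 10 tested members of the oligodendrocyte and myelin list were higher, over all genes and when adjusted over the list alone, with a median of 4.59. All 7 tested homeostatic microglia genes were also higher in white matter on both counts (median 1.94), among them P2RY12 (1.43 ± 0.15), a purine receptor of resting microglia. White matter was lower in FREM3 (-6.28 ± 0.40, adjusted p = 5.71e-06), in the kinase gene CAMK2A of excitatory neurons (-3.20 ± 0.61, adjusted p = 0.000977) and in SNAP25, which codes for a synaptic vesicle fusion protein (-2.63 ± 0.74, adjusted p = 0.00912). All 13 pan-neuronal genes were lower, also when adjusted over the list alone (median -2.47). Without control white matter replicates 1 and 3 the median was -3.77, and the fold changes were -4.42 for SNAP25 and -4.70 for CAMK2A. Across the genome 9381 of 15406 tested genes differed, 4550 higher and 4831 lower in white matter. Hippocampus was higher than prefrontal cortex in the water and glycerol channel AQP3 (6.34 ± 0.36, adjusted p = 7.01e-06) and in PROX1 (2.20 ± 0.36, adjusted p = 0.00214), a transcription factor of dentate granule cells, and lower in FREM3 (-6.58 ± 0.41). Of the 11 hippocampal identity genes 7 were higher and none was lower over all genes (median 1.24). When adjusted over the list alone 7 were higher and 2 lower. The choroid plexus and ependyma list had a larger median (2.65), with 5 of 8 members higher and 0 lower on both counts. In total 2306 genes differed, 1183 higher and 1123 lower in hippocampus, a number that fell to 1261, 1480 and 1430 without control animals 3, 4 and 5. Against hippocampus, white matter was higher in MBP (4.20 ± 0.47) and lower in C1QL2 (-2.78 ± 0.30, adjusted p = 3.63e-05), which codes for a secreted synaptic protein, and in the vesicular glutamate transporter SLC17A7 (-3.32 ± 0.64, adjusted p = 0.00125, and -4.56 without those 2 libraries). That comparison called 8616 genes, 4332 higher and 4284 lower.

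White matter dissections were not uniform in the control animals. The mean of the pan-neuronal genes was 8.61 log2 CPM in control white matter replicate 1 and 7.56 in replicate 3, against 4.92 to 5.31 in the other 3 control libraries. It averaged 6.30 ± 1.68 (SD, n = 5) in control, 5.20 ± 0.358 in fWBI and 5.17 ± 0.292 in TBI white matter. Any grey matter in replicates 1 and 3 would lower, in controls, lists that are higher in white matter than in prefrontal cortex. Such lists, by median, included reactive astrocyte (1.56), MHC class II and antigen presentation (1.36) and complement genes (1.04). This could add to rises and hide falls in white matter of both irradiation groups. It is not separated from them unless values without these libraries are given.

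**Figure D1:**
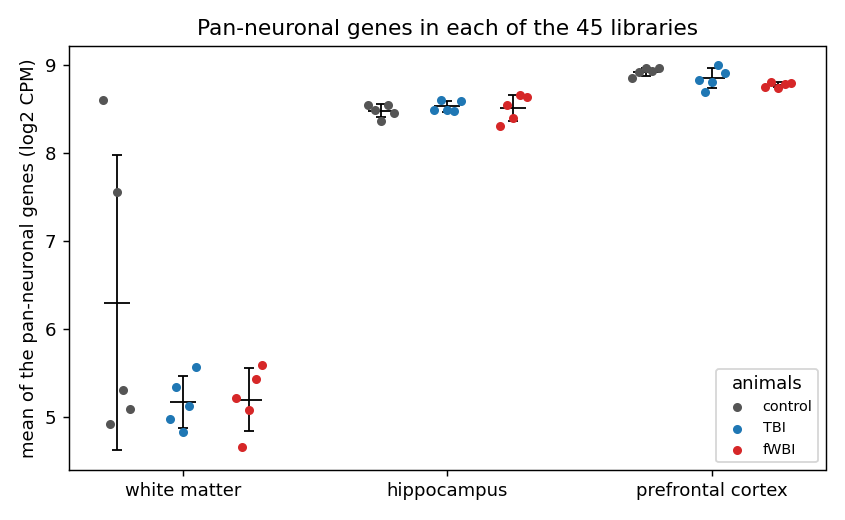
Mean log2 CPM of the pan-neuronal genes in each of the 45 libraries, by region and animal group; points are libraries, the horizontal bar is the group mean and the whiskers are 1 SD (n = 5). Control white matter replicates 1 and 3, at 8.61 and 7.56, sit above the other white matter libraries, while control hippocampus averaged 8.48 and control prefrontal cortex 8.93.

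After fWBI, white matter lost transcripts of the oligodendrocyte lineage's immature cells. MYT1 (ENSMMUG00000002315), a zinc finger transcription factor of oligodendrocyte progenitors and developing neurons, fell by 4.45 ± 0.27 on the log2 scale (adjusted p = 1.99e-07), and TNR (ENSMMUG00000015723), the extracellular matrix glycoprotein tenascin-R, fell by 4.61 ± 0.31 (adjusted p = 3.13e-07). GPR17 (ENSMMUG00000004180), a receptor of committed oligodendrocyte precursors, fell by 2.52 ± 0.25, PCDH15 by 3.80 ± 0.38 and LHFPL3 by 2.30 ± 0.23, with adjusted p from 7.63e-06 to 1.04e-05. Of 11 oligodendrocyte precursor genes 9 fell and none rose, both over all genes and when adjusted over the list alone. Its members' median was -1.46 (fry adjusted p = 4.73e-06). Genes of mature myelin did not pass the test: 0 of 10 list members over all genes and 0 adjusted over the list alone, with a median of -0.19 (fry adjusted p = 0.586, and 0.0497 without control replicate 1), and MBP at -0.62 ± 0.23 (adjusted p = 0.071). MBP passed without control replicate 1, whose pan-neuronal mean was 8.61 (-0.74, adjusted p = 0.0234), and without fWBI replicate 1 (-0.77, adjusted p = 0.0345). The mean of the myelin list was 9.74 and 10.49 log2 CPM in control replicates 1 and 3, and 10.78 to 10.96 in control replicates 2, 4 and 5. After fWBI it was 10.12 to 10.64, below replicates 2, 4 and 5 in every library, so a fall of myelin genes is not excluded. NKAIN4 (ENSMMUG00000009231), which codes for a membrane protein that binds the sodium pump, fell by 5.46 ± 0.53 (adjusted p = 7.26e-06). The fall of 8 of 13 cholesterol biosynthesis genes (10 when adjusted over the list alone, median -0.76, fry adjusted p = 0.00386) included the synthase gene HMGCS1 (-1.27 ± 0.23, adjusted p = 0.00136); that list's adjusted p = 0.181 with an estimated correlation.

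Myeloid, antigen presentation and complement genes rose in the same libraries. CD74 (ENSMMUG00000009113), the MHC class II invariant chain, rose by 3.05 ± 0.22 (adjusted p = 3.94e-07), MAMU-DRB1 by 3.05 ± 0.32 and MAMU-DMB by 3.16 ± 0.26. All 7 tested MHC class II and antigen presentation genes rose, also when adjusted over the list alone (median 2.36, fry adjusted p = 4.73e-06); reads of the MHC genes could be shared among near-identical copies. GPNMB (ENSMMUG00000012648), a glycoprotein of lipid-laden phagocytes, rose by 7.08 ± 0.66 (adjusted p = 5.04e-06) and the lysosomal glycoprotein gene CD68 by 3.70 ± 0.39. Of 16 genes of activated and lipid-laden microglia and macrophages 13 rose on both counts. The list's median was 2.20 (fry adjusted p = 0.000351, and adjusted p = 0.0969 with an estimated correlation). LYZ, the lysozyme gene, rose by 4.75 ± 0.42 and the macrophage lectin SIGLEC1 by 4.08 ± 0.38; 3 of 6 perivascular macrophage genes rose, and 4 when adjusted over the list alone. Its median was 1.75 (fry adjusted p = 0.000283, and adjusted p = 0.0846 with an estimated correlation). The complement genes CFB (2.69 ± 0.18, adjusted p = 3.13e-07) and C1QC (2.80 ± 0.29) were among 10 of 12 complement genes that rose, 11 when adjusted over the list alone. The median was 1.48 (fry adjusted p = 1.01e-05). The monocyte chemoattractant CCL2 (ENSMMUG00000000288) rose by 4.97 ± 0.31 (adjusted p = 1.99e-07). Homeostatic microglia genes went both ways: of 7, 1 fell and 1 rose over all genes (2 higher and 1 lower adjusted over the list alone), and P2RY12 fell by 1.36 ± 0.21 (adjusted p = 0.000393), with a list median of 0.0034 and a fry adjusted p of 0.954 for 1 direction and 0.00366 for either.

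Reactive astrocyte genes rose and several homeostatic astrocyte genes fell in fWBI white matter. SERPINA3 (ENSMMUG00000011218), an acute-phase protease inhibitor, rose by 5.21 ± 0.42 (adjusted p = 1.28e-06), the intermediate filament gene VIM by 2.94 ± 0.24 and the copper-carrying ferroxidase gene CP by 4.43 ± 0.32. Of 12 reactive astrocyte genes 11 rose on both counts. Its members' median was 2.05 (fry adjusted p = 4.73e-06). Of 13 astrocyte genes 6 fell and 1 rose (6 and 2 when adjusted over the list alone, median -0.60, fry adjusted p = 0.00317, adjusted p = 0.247 with an estimated correlation), including the glutamate transporter SLC1A2 (-2.25 ± 0.23, adjusted p = 1.31e-05). Interferon-stimulated genes rose, 7 of 14 over all genes and 8 adjusted over the list alone, among them OAS2 (1.82 ± 0.19). Their median was 0.72 (fry adjusted p = 0.000283, adjusted p = 0.0759 with an estimated correlation). In controls their median was 0.677 higher in white matter than in prefrontal cortex. Any grey matter in control replicates 1 and 3 was thus not separated from this rise. Of 14 p53 target genes 7 rose, and 10 when adjusted over the list alone (median 0.42, fry adjusted p = 0.000118); EDA2R, a receptor of the tumour necrosis factor family, rose by 2.30 ± 0.40 (adjusted p = 0.00084). The cell cycle inhibitor CDKN2B rose by 2.69 ± 0.33 (adjusted p = 5.5e-05), 1 of 4 of 9 senescence and secreted factor genes that rose on both counts. The list's median was 0.49 (fry adjusted p = 0.000159, and adjusted p = 0.0605 with an estimated correlation).

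Pan-neuronal and postsynaptic genes were lower in fWBI than in control white matter. For the pan-neuronal genes this difference followed control replicates 1 and 3. Of 13 pan-neuronal genes 7 were lower, 10 adjusted over the list alone, with a median of -2.15 and a fry adjusted p of 0.262. Of 16 glutamate receptor and postsynaptic genes 12 were lower (15 adjusted over the list alone, median -1.86, fry adjusted p = 0.00857, adjusted p = 0.272 with an estimated correlation), including the AMPA receptor subunit GRIA4 (-2.54 ± 0.20, adjusted p = 9.71e-07, and -2.23 without replicates 1 and 3, adjusted p = 2.71e-06). Without those 2 control libraries 0 of 13 pan-neuronal genes passed (median 0.203), and 5 of the postsynaptic genes were lower. Its median was -0.57 (fry adjusted p = 0.00547). NRGN, a calmodulin-binding protein of dendritic spines, was at -2.26 ± 0.52 (adjusted p = 0.00737) with them and at -0.73 (adjusted p = 0.0817) without them. The oligodendrocyte precursor median was -1.46 with and -1.62 without them.

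In total 2537 of 15235 genes differed between fWBI and control white matter, 1340 higher and 1197 lower, and 4485 had an unadjusted p under 0.05 against 762 given by chance. Without control replicates 1 and 3 the count was 1674, 1124 higher and 550 lower, and 1353 genes were called both ways; with only the 2 groups compared it was 1639, and with all 45 libraries in 1 fit 4062.

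**Figure D2:**
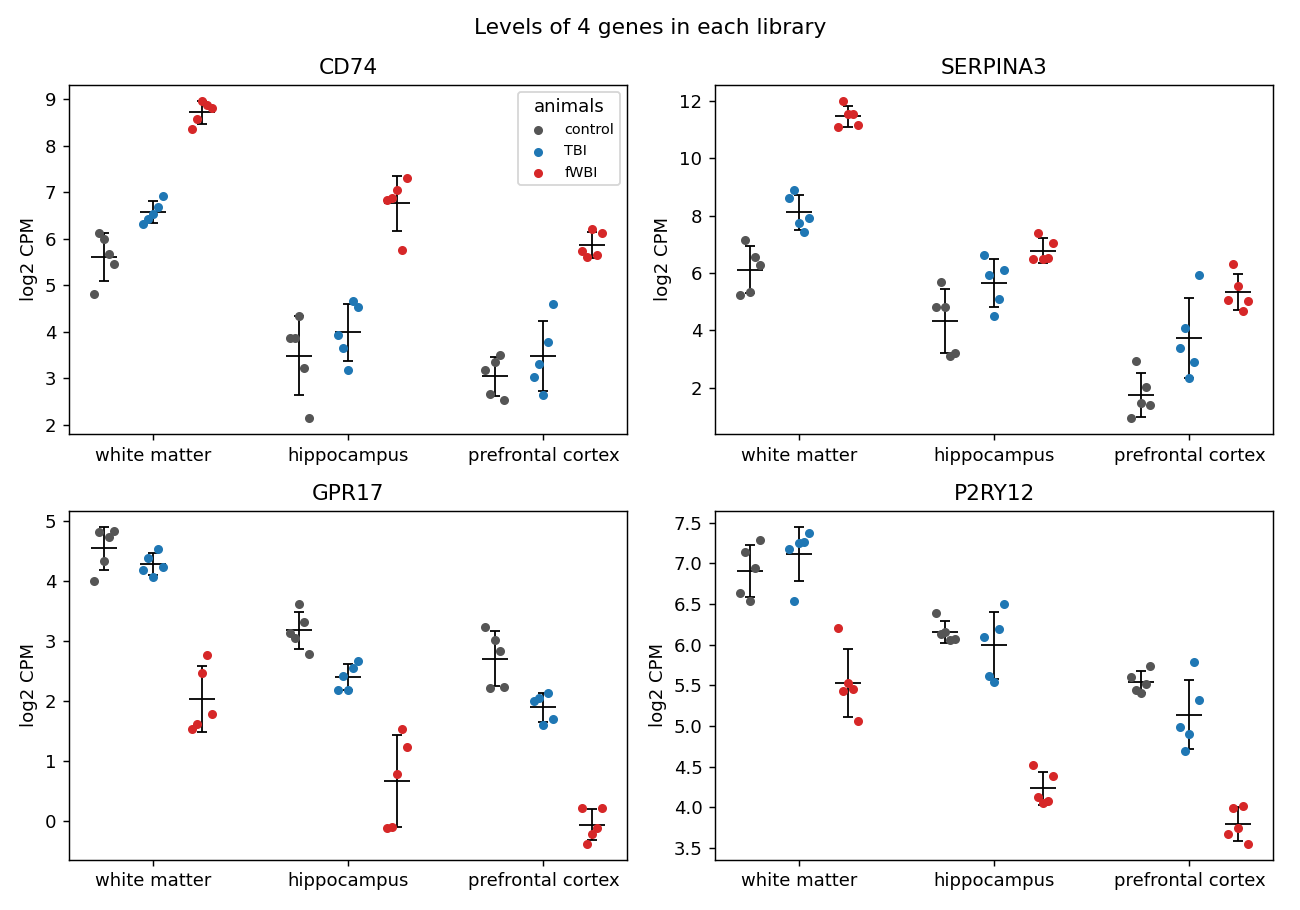
Log2 CPM of CD74, SERPINA3, GPR17 and P2RY12 in each library, by region and animal group; points are libraries, the horizontal bar is the group mean and the whiskers are 1 SD (n = 5). In white matter the 5 fWBI libraries lie between 8.35 and 8.95 for CD74, where the controls lie between 4.81 and 6.12.

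In hippocampus fWBI lowered oligodendrocyte precursor genes and raised antigen presentation, myeloid and matrix genes. P2RY12 (ENSMMUG00000001105) fell by 1.93 ± 0.17 (adjusted p = 1.97e-05), NKAIN4 by 3.94 ± 0.36 (adjusted p = 3.25e-05), GPR17 by 2.50 ± 0.30 (adjusted p = 0.000521) and CSPG4, the NG2 proteoglycan of oligodendrocyte precursors, by 1.27 ± 0.22 (adjusted p = 0.00947, and 0.0696 with only the 2 groups fitted). CD74 rose by 3.19 ± 0.39 (adjusted p = 0.000794), LYZ by 2.27 ± 0.23 (adjusted p = 7.56e-05) and the fibrillar collagen COL1A1 by 2.77 ± 0.33 (adjusted p = 0.000556). Of 11 oligodendrocyte precursor genes 4 fell, and 8 when adjusted over the list alone. The median was -0.89 (fry adjusted p = 4.03e-05). Of 7 homeostatic microglia genes 2 fell over all genes, P2RY12 and SELPLG (-1.37 ± 0.21), while 3 fell and 1 rose when adjusted over the list alone. Its members' median was -0.49 (fry adjusted p = 0.00349, and adjusted p = 0.128 with an estimated correlation). Genes of activated and lipid-laden microglia and macrophages rose, 3 of 15 over all genes and 8 adjusted over the list alone (median 0.55, fry adjusted p = 0.000354), including the scavenger receptor MSR1 (2.78 ± 0.29, adjusted p = 0.000111). All 6 perivascular macrophage genes rose when adjusted over the list alone and 3 over all genes, SIGLEC1 among them (1.95 ± 0.26; list median 0.75, fry adjusted p = 8.45e-05). Of 7 MHC class II and antigen presentation genes 3 rose, and 6 adjusted over the list alone. The list's median was 0.73 (fry adjusted p = 0.00135). The fibroblast, meninges and extracellular matrix list had 10 of 18 members higher, 12 adjusted over the list alone (median 1.02, fry adjusted p = 0.000367), among them COL3A1 (2.75 ± 0.44) and FN1, which codes for fibronectin (1.15 ± 0.17).

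Complement genes rose in hippocampus too, 3 of 12 over all genes, with 8 higher and 1 lower adjusted over the list alone (median 0.65, fry adjusted p = 0.00699, adjusted p = 0.0841 with an estimated correlation), among them C3AR1 (1.44 ± 0.20, adjusted p = 0.00147). Of 14 interferon-stimulated genes 2 rose and 6 adjusted over the list alone. Its median was 0.64 (fry adjusted p = 0.00763, and adjusted p = 0.0689 with an estimated correlation). No reactive astrocyte gene passed over all genes, 5 of 12 were higher when adjusted over the list alone (median 0.55, fry adjusted p = 0.00801, adjusted p = 0.0605 with an estimated correlation), and GFAP stood at 0.42 ± 0.18 (adjusted p = 0.372) and VIM at 0.84 ± 0.20 (adjusted p = 0.0648). VIM passed without control replicate 2 (0.98, adjusted p = 0.0172) and without fWBI replicate 4 (0.94, adjusted p = 0.0246). Of 13 pan-neuronal genes 0 passed over all genes and 1 was lower adjusted over the list alone. The median was 0.031 (fry adjusted p = 0.986). In total 111 of 15357 genes differed, 79 higher and 32 lower, with 1710 at an unadjusted p under 0.05 against 768 given by chance. The count was 70 without control replicate 1, 264 without control replicate 2 and 73 without fWBI replicate 2, and DESeq2 called 271.

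In prefrontal cortex fWBI also lowered oligodendrocyte precursor genes. OLIG2 (ENSMMUG00000017652), a transcription factor of the oligodendrocyte lineage, fell by 2.26 ± 0.16 (adjusted p = 1.55e-06), GPR17 by 3.08 ± 0.26 (adjusted p = 7.31e-06), NKAIN4 by 3.86 ± 0.32 (adjusted p = 5.68e-06), P2RY12 by 1.75 ± 0.18 (adjusted p = 5.6e-05) and SELPLG, a selectin ligand of leukocytes and microglia, by 2.34 ± 0.22 (adjusted p = 2.87e-05). The matrix metalloproteinase gene MMP2 rose by 2.37 ± 0.23 (adjusted p = 4.3e-05), CLEC7A, the phagocyte receptor dectin-1, by 3.45 ± 0.48 (adjusted p = 0.00143) and CD74 by 2.82 ± 0.31 (adjusted p = 0.00013). Of 11 oligodendrocyte precursor genes 5 fell, 10 adjusted over the list alone. Its members' median was -0.93 (fry adjusted p = 6.09e-06). Of 7 homeostatic microglia genes 3 fell, with 4 lower and 1 higher adjusted over the list alone. The list's median was -0.59 (fry adjusted p = 0.000588, and adjusted p = 0.0689 with an estimated correlation). Of 7 MHC class II and antigen presentation genes 3 rose on both counts. Its median was 0.92 (fry adjusted p = 0.000136). Genes of activated and lipid-laden microglia and macrophages rose, 2 of 15 over all genes and 5 adjusted over the list alone (median 0.49, fry adjusted p = 0.000563), and so did 2 of 6 perivascular macrophage genes, 5 adjusted over the list alone. The median was 0.87 (fry adjusted p = 0.000283). The extracellular matrix list had 8 of 18 members higher, 11 adjusted over the list alone (median 0.74, fry adjusted p = 0.000756), COL3A1 among them (2.46 ± 0.34, adjusted p = 0.00128).

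Reactive astrocyte genes rose in prefrontal cortex, 4 of 11 over all genes and 8 adjusted over the list alone. Its members' median was 0.86 (fry adjusted p = 0.000907). SERPINA3 rose by 3.56 ± 0.65 (adjusted p = 0.0134) and GFAP, the astrocyte intermediate filament, by 1.08 ± 0.21 (adjusted p = 0.0151). Without control replicate 3 neither passed (SERPINA3 3.44, adjusted p = 0.0515; GFAP 1.04, adjusted p = 0.0575), nor did SERPINA3 without control replicate 1 (3.39, adjusted p = 0.056). Of 12 complement genes 3 rose, with 6 higher and 1 lower adjusted over the list alone. The list's median was 0.54 (fry adjusted p = 0.0158, and adjusted p = 0.147 with an estimated correlation). Of 13 pan-neuronal genes 0 passed over all genes and 0 adjusted over the list alone (median -0.14, fry adjusted p = 0.0979, and 0.0124 without control replicate 1). In total 179 of 15531 genes differed, 124 higher and 55 lower, with 2112 at an unadjusted p under 0.05 against 777 given by chance. The count was 73 without control replicate 3, 118 without control replicate 5, and 107, 94 and 99 without fWBI replicates 1, 2 and 3; it was 66 without control animal 5 and fWBI animals 1 and 4, which held the largest shares of counts in IDs without a symbol of their groups in each region, and 442 with DESeq2.

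Some genes changed after fWBI in all 3 regions. Of 14430 genes tested in each, 32 rose and 10 fell everywhere, where independent lists would share 0.046 and 0.0091. CD74, MAMU-DRB1, LYZ, CD14, CLEC7A, C3AR1, COL3A1, COL4A1, FN1 and MMP2 were among those that rose, and NKAIN4, GPR17, P2RY12 and PCDH15 among those that fell. White matter and hippocampus shared 50 rises and 21 falls (5.67 and 2.53 from independent lists), and hippocampus and prefrontal cortex 43 and 13 (0.572 and 0.112). The libraries of the 3 regions came from the same animals, so these lists are not independent.

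The fWBI effect differed in size between white matter and the grey matter regions for many genes, by a direct test of the difference. MYT1 fell further in white matter than in prefrontal cortex (difference -3.60 ± 0.33, adjusted p = 1.86e-08) and than in hippocampus (-3.92 ± 0.32, adjusted p = 3.6e-09), and so did TNR (-3.84 ± 0.41 and -3.83 ± 0.41). The phagocyte receptor FCGR2A rose further in white matter (5.85 ± 0.64 against prefrontal cortex and 6.04 ± 0.59 against hippocampus), as did VIM (2.10 ± 0.23 and 2.09 ± 0.23), LYZ (2.79 ± 0.35 and 2.40 ± 0.33), CCL2 (3.07 ± 0.85, adjusted p = 0.0184, and 3.29 ± 0.62, adjusted p = 0.000936) and CFB (1.17 ± 0.29, adjusted p = 0.00922, and 1.56 ± 0.28, adjusted p = 0.000526). GPNMB rose further in white matter than in prefrontal cortex (5.72 ± 0.58, adjusted p = 1.38e-07), while ASIC4, an ion channel subunit, fell further (-3.27 ± 0.28, adjusted p = 5.61e-09). Against hippocampus the white matter effect was also larger for SERPINA3 (2.98 ± 0.55) and MAMU-DMB (2.46 ± 0.32), and lower for COL1A1 (-1.80 ± 0.53, adjusted p = 0.0295), COL3A1 (-1.28 ± 0.38, adjusted p = 0.0307) and CA10, a carbonic anhydrase-related protein (-3.27 ± 0.35). OLIG2 fell less in white matter than in prefrontal cortex (1.58 ± 0.28, adjusted p = 0.000377) and hippocampus (0.87 ± 0.27, adjusted p = 0.0389). For CD74 the differences were 0.26 ± 0.36 (adjusted p = 0.725) and -0.17 ± 0.35 (adjusted p = 0.854), and for GPR17 0.49 ± 0.36 (adjusted p = 0.438) and -0.01 ± 0.63 (adjusted p = 0.994); a p that misses the threshold does not show equal effects.

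The effect in white matter differed from that in prefrontal cortex for 1654 of 16614 genes (757 higher, 897 lower) and from that in hippocampus for 1488 (686 higher, 802 lower). Without control white matter replicates 1 and 3 these counts were 1055 and 925; they were 1095 and 872 without control animal 3, and 1014 and 837 without fWBI animal 2. Between hippocampus and prefrontal cortex edgeR called 0 genes, with 299 at an unadjusted p under 0.05 against 831 given by chance. That is fewer than chance gives, so the test may be too strict here. Its spread was estimated on all 45 libraries, the uneven control white matter included. These 0 calls therefore do not show that both regions responded alike.

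After TBI, white matter held a small set of higher genes. CFB rose by 1.28 ± 0.18 (adjusted p = 0.0154), GPX1, a glutathione peroxidase, by 1.40 ± 0.22 (adjusted p = 0.0301), CLEC5A, a myeloid lectin receptor, by 2.32 ± 0.36 (adjusted p = 0.0301), CCL2 by 1.79 ± 0.31 (adjusted p = 0.0394), and the interferon-inducible GTPase genes GBP3 and GBP7 by 0.86 ± 0.14 and 0.99 ± 0.16 (adjusted p = 0.031 for both). The complement list was higher as a group, with 1 of 12 members past the threshold and 8 adjusted over the list alone. Its median was 0.81 (fry adjusted p = 0.00349, and adjusted p = 0.0586 with an estimated correlation). Reactive astrocyte genes had 0 of 12 past the threshold and 7 higher adjusted over the list alone (median 0.67, fry adjusted p = 0.00983, adjusted p = 0.0809 with an estimated correlation), with GFAP at 0.75 ± 0.21 (adjusted p = 0.14) and VIM at 0.70 ± 0.22 (adjusted p = 0.14). MHC class II and antigen presentation genes had 0 of 7 past it and 4 higher adjusted over the list alone (median 0.68, fry adjusted p = 0.00825, adjusted p = 0.1 with an estimated correlation), with CD74 at 0.91 ± 0.20 (adjusted p = 0.12) and its transactivator CIITA at 0.57 ± 0.26 (adjusted p = 0.267). In control animals the medians of the complement, reactive astrocyte and antigen presentation lists were higher in white matter than in prefrontal cortex (1.04, 1.56 and 1.36). Any grey matter in control replicates 1 and 3 would thus lower them in controls, and this was not separated from a rise after TBI. Oligodendrocyte precursor genes had 0 of 11 past the threshold on either count, 0 adjusted over the list alone. The median was -0.072 (fry adjusted p = 0.947), with GPR17 at -0.29 ± 0.23 (adjusted p = 0.543). Precursor genes were also higher in control white matter than in prefrontal cortex (median 1.16). Any grey matter in control replicates 1 and 3 would thus lower them in controls too, so a fall after TBI is not excluded. Pan-neuronal genes had 0 of 13 past the threshold over all genes and 13 lower adjusted over the list alone. Their median was -2.25 (fry adjusted p = 0.24), a difference that again followed control replicates 1 and 3. In total 11 of 15235 genes passed, 10 higher and 1 lower, with 2749 at an unadjusted p under 0.05. The count was 0 without control replicate 1 or 3, without TBI replicate 1 or 3 and without control replicates 1 and 3 together; it was 25, 3 and 2 without control replicates 2, 4 and 5, 6, 6 and 4 without TBI replicates 2, 4 and 5, and 783 with DESeq2, of which 544 were lower.

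In hippocampus no gene passed the threshold between TBI and control. The smallest p-values belonged to RBM46, an RNA-binding protein (1.72 ± 0.27, adjusted p = 0.137), and to NAP1L1, OXR1, NMD3 and HMGCLL1, with values between 0.32 ± 0.062 (OXR1) and 0.57 ± 0.11 (HMGCLL1) and an adjusted p of 0.237 each. RBM46 passed without control replicate 2 (1.94, adjusted p = 0.0368) and without TBI replicate 5 (1.86, adjusted p = 0.0366). Astrocyte genes had 0 of 13 past the threshold and 1 higher adjusted over the list alone (median 0.14, fry adjusted p = 0.0404, adjusted p = 0.133 with an estimated correlation), with AQP4 at 0.14 ± 0.13 (adjusted p = 0.7) and ALDH1L1 at 0.14 ± 0.098 (adjusted p = 0.606). That list's adjusted p was 0.0579, 0.0681 and 0.0665 without control replicates 3, 4 and 5, and 0.0679, 0.0768 and 0.0644 without TBI replicates 3, 4 and 5. Oligodendrocyte precursor genes had a median of -0.22 (fry adjusted p = 0.134, and 0.025 without control replicate 2), with 0 of 11 past the threshold over all genes and 0 adjusted over the list alone. GPR17 was at -0.82 ± 0.27 (adjusted p = 0.359), with all 5 TBI libraries below every control library. The count of genes by edgeR was 0 of 15357, with 1634 at an unadjusted p under 0.05 against 768 given by chance; DESeq2 called 59, limma-voom 1, and edgeR 3 without control replicate 2 and 1 without TBI replicate 5.

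In prefrontal cortex the TBI animals also gave no gene past the threshold. COL11A2, a fibrillar collagen, was at -1.15 ± 0.17 (adjusted p = 0.066), and the chaperone gene DNAJB5 (-1.07 ± 0.18), RNF112 (-0.54 ± 0.097), the transcription factor ETV4 (-1.60 ± 0.29) and ST6GAL2 (-0.67 ± 0.12) followed with an adjusted p of 0.068. COL11A2 passed without control replicate 1 (-1.08, adjusted p = 0.0484), control replicate 2 (-1.10, adjusted p = 0.0313) or TBI replicate 3 (-1.26, adjusted p = 0.0444), and DNAJB5 (-1.18, adjusted p = 0.0218) and ETV4 (-1.75, adjusted p = 0.0313) without control replicate 2. As a group, cholesterol biosynthesis genes were lower (median -0.25, fry adjusted p = 0.00466), with 0 of 13 past the threshold on either count (0 adjusted over the list alone) and HMGCS1 at -0.34 ± 0.13 (adjusted p = 0.329). Reactive astrocyte genes were higher as a group (median 0.66, fry adjusted p = 0.0136, adjusted p = 0.0759 with an estimated correlation), with 0 of 11 past the threshold and 5 adjusted over the list alone, GFAP at 0.76 ± 0.20 (adjusted p = 0.146) and VIM at 0.50 ± 0.18 (adjusted p = 0.285). GPR17 was at -0.88 ± 0.22 (adjusted p = 0.125), again with all 5 TBI libraries below every control library. The count of genes by edgeR was 0 of 15531, with 1819 at an unadjusted p under 0.05 against 777 given by chance; DESeq2 called 241 and limma-voom 162, and edgeR called 5, 23 and 1 without control replicates 1, 2 and 5 and 1 without TBI replicate 3.

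The TBI effect differed between white matter and prefrontal cortex for 5 of 16614 genes, 4 higher and 1 lower, 3 of which had a symbol: ADAMTSL2, a secreted matrix protein (1.67 ± 0.29, adjusted p = 0.0256), the dehydrogenase gene DHRS4 (1.44 ± 0.26, adjusted p = 0.0256) and the potassium channel subunit KCNMB4 (1.03 ± 0.20, adjusted p = 0.0495). That count was 3, 33, 0, 1 and 90 without control animals 1 to 5, and 0, 1, 2 and 1 without TBI animals 2 to 5. White matter and hippocampus differed for 1 gene without a symbol; this count was 6, 3 and 200 without control animals 2, 4 and 5, 2 without TBI animal 2 or 4, and 0 without any other single animal. For hippocampus against prefrontal cortex edgeR called 0 genes, with 434 at an unadjusted p under 0.05 against 831 given by chance. Here too the small p-values were fewer than chance gives, so 0 calls do not show equal effects.

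Compared directly, fWBI white matter was lower than TBI white matter in MYT1 (-3.99 ± 0.27, adjusted p = 7.99e-07), TNR (-4.58 ± 0.31), NKAIN4 (-5.00 ± 0.54) and DLL3, a Notch ligand (-3.80 ± 0.40), and higher in CHIT1, the chitinase of lipid-laden macrophages (7.14 ± 0.88, adjusted p = 0.000133) and FBXO40, an F-box protein (5.85 ± 0.65, adjusted p = 5.13e-05). The oligodendrocyte precursor list was lower in fWBI in all 3 regions, by fry. Its counts were 8 of 11 in white matter (9 adjusted over the list alone, median -1.59, fry adjusted p = 4.73e-06), 2 in hippocampus (7, median -0.75, adjusted p = 0.000159) and 5 in prefrontal cortex (9, median -0.98, adjusted p = 1.34e-05). MHC class II and antigen presentation genes were higher in fWBI: 5 of 7 in white matter (7 adjusted over the list alone, median 1.79, fry adjusted p = 8.43e-05), 3 in hippocampus (5, median 0.72, adjusted p = 0.0014) and 3 in prefrontal cortex (4, median 1.02, adjusted p = 0.000658). In hippocampus P2RY12 was lower (-1.80 ± 0.17, adjusted p = 9.92e-05), and COL1A1 (3.05 ± 0.34) and CD74 (2.76 ± 0.37) were higher; in prefrontal cortex OLIG2 (-2.12 ± 0.16, adjusted p = 3.84e-06) and SELPLG (-1.97 ± 0.22) were lower, and MMP2 (2.14 ± 0.23) and CD74 (2.25 ± 0.30) higher. In total 1117 genes differed in white matter (732 higher and 385 lower in fWBI; 743 without fWBI replicate 2), 52 in hippocampus (38 and 14) and 45 in prefrontal cortex (33 and 12). The hippocampal count was 33 without TBI replicate 2, 34 without fWBI replicate 2 and 33 without fWBI replicate 3, and the cortical count 29 without TBI replicate 2 and 28 without fWBI replicate 2.

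Both irradiation groups were compared with the same controls, so chance alone makes their fold changes agree. In white matter 8 genes rose in both comparisons (0.88 from independent lists) and 0 fell in both (0.0786). Across 15235 genes, which are not independent replicates, the fold changes of fWBI and TBI correlated at r = 0.669, where 20 simulated unchanged groups averaged 0.505 against the same controls, and the covariance was 0.283 against a simulated 0.0427 ± 0.0012 (SD). The simulations drew each gene independently, with the same spread in all groups. Their SD therefore leaves out differences shared by many genes, such as those of control replicates 1 and 3. With the controls split between the comparisons r was 0.508 (median of 20 splits, range 0.148 to 0.591) and the median number of shared genes 0, with 360 in the highest split; without control replicates 1 and 3, r was 0.478 against a simulated 0.635 with the 3 controls left, and the covariance 0.14 against 0.0635 ± 0.0033 (SD). In hippocampus 0 genes were shared, r was 0.5 against a simulated 0.514, and 0.0886 with split controls; the covariance was 0.0565 against a simulated 0.0317. In prefrontal cortex 0 genes were shared, r was 0.635 against a simulated 0.508, and 0.214 with split controls; the covariance was 0.0723 against 0.0306. The shared count in white matter was 0 without control replicate 1 or 3, 19 without replicate 2 and 2 without replicate 4 or 5; in hippocampus it was 1 without control replicate 2, and in prefrontal cortex 4, 17 and 1 without control replicates 1, 2 and 5.

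**Figure D3:**
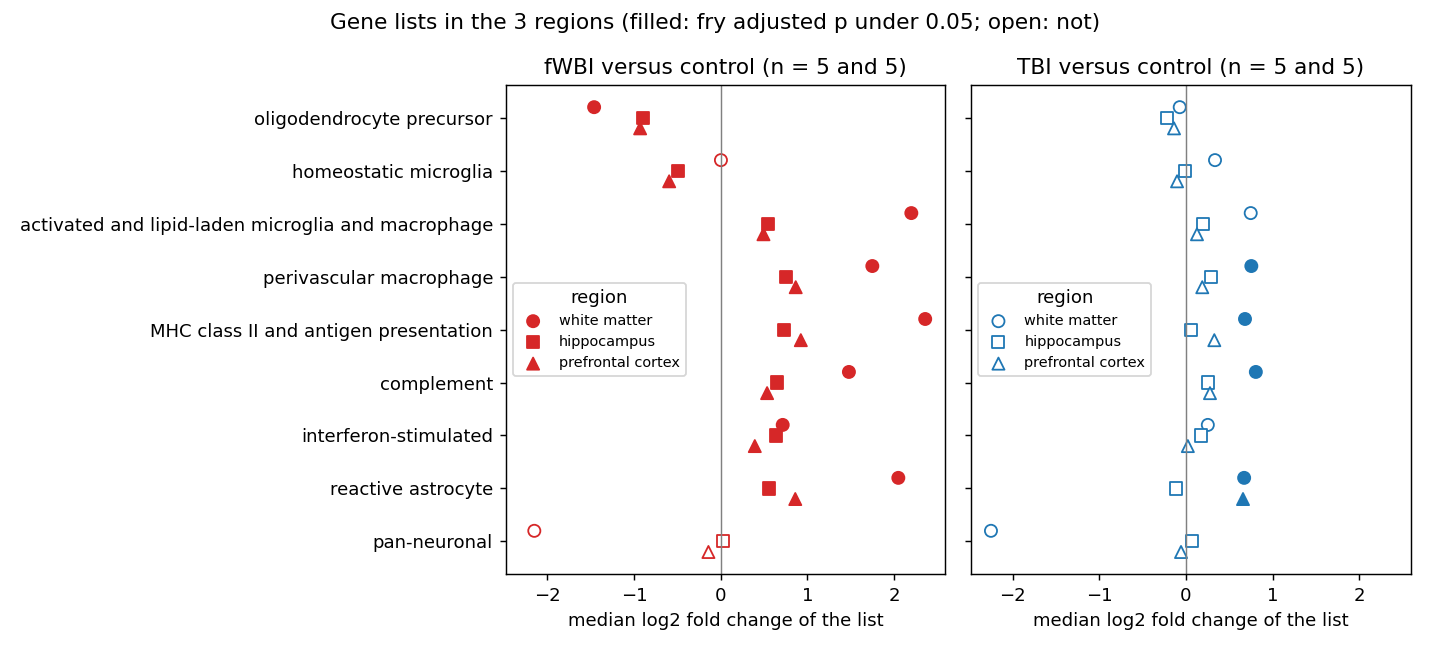
Median log2 fold change of 9 gene lists after fWBI and after TBI in white matter, hippocampus and prefrontal cortex (n = 5 irradiated and 5 control animals each); filled symbols mark lists with a fry adjusted p under 0.05. The oligodendrocyte precursor medians after fWBI are -1.46, -0.89 and -0.93, and after TBI -0.072, -0.22 and -0.14; the pan-neuronal medians in white matter rest on control replicates 1 and 3.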

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

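The tests given here for neuronal, precursor and myeloid genes, with the removal of 2 control white matter libraries, were chosen only after the result was seen; so was the rule that a setting tests nothing unless it moves 5% of genes by more than their standard error.

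The first pattern was the lower level of neuronal genes in white matter after fWBI, with a pan-neuronal median of -2.15. Without control white matter replicates 1 and 3, picked for their high neuronal genes, the median was 0.203 and 0 of 13 genes were called, which their choice fixed in advance. Grey matter would also lower myelin genes there: the oligodendrocyte and myelin mean was 9.74 and 10.49 log2 CPM in these 2 libraries, the higher of them -0.29 from the lowest of the other 3 controls, but 10.49 lay within the range after fWBI (10.12 to 10.64). Grey matter in these 2 dissections is a candidate explanation, for the pan-neuronal median of -2.25 after TBI as well, but other differences of these 2 animals were not separated from it. The cause stays open for the postsynaptic genes, of which 5 of 16 were lower without these libraries. Which cells lost these transcripts was not tested, and oligodendrocyte precursor genes fell in the same fWBI libraries.

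The second pattern was the lower level of oligodendrocyte precursor genes after fWBI in 3 regions. The covariate for the grey or white matter share was not a measured share. It was the mean of the pan-neuronal list in white matter, and of the myelin list in hippocampus and prefrontal cortex, in the same libraries. With this covariate the median was -1.68 in white matter, where it moved 28% of genes. A share that the pan-neuronal mean tracks therefore does not account for the whole change there. In hippocampus (-0.895) and prefrontal cortex (-0.8) the covariate moved 0.026 and 0.998% and so tested nothing. Control white matter exceeded hippocampus by medians of 3.78 in myelin and 1.01 in precursor genes, and prefrontal cortex by 4.59 and 1.16. A lower white matter share would thus lower myelin genes more. The myelin mean was 6.945 ± 0.758 log2 CPM (SD) in control hippocampus and 6.942 ± 0.643 after fWBI. In prefrontal cortex it was 6.103 ± 0.788 and 5.706 ± 0.419. These values argue against the share as the whole cause in these regions. Without control animal 5 and fWBI animals 1 and 4 the weakest regional median was -0.9, so these animals do not account for the whole pattern. Thinning every library to the smallest total of its region moved at most 0.674% of genes, so by the rule above it tested nothing. At these equal totals the medians were still -1.43 in white matter, -0.895 in hippocampus and -0.974 in prefrontal cortex. Before thinning they were -1.46, -0.891 and -0.929, which argues against different depths as the cause of the list's fall. Fewer or less active precursors 12 months after fWBI stay open, since counts from homogenised tissue do not separate cell number from expression per cell. Dose and time since exposure were not tested as causes, since both differed from TBI, nor were age, sex or sequencing batch, which were not used here and may differ between the groups.

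The third pattern was the rise of myeloid and antigen presentation genes after fWBI in 3 regions. Blood left in the tissue would bring S100A9, whose highest regional mean after fWBI was 0.488 CPM, while CD74 rose by 383 CPM in white matter, 103 in hippocampus and 49.9 in prefrontal cortex; the log2 fold change of HBA was too variable to decide (-0.285 ± 1.44, 1.07 ± 1.61 and -0.592 ± 1.36). Thinning to equal totals tested nothing by the rule above. The smallest log2 fold change of CD74 was 2.81 after it, against 2.82 before, so different totals do not account for the rise of CD74. Other genes of this pattern were not examined after thinning, and depth stays open for them. More microglia of every kind would raise homeostatic genes as much as activated ones (medians 2.2 in white matter, 0.546 in hippocampus and 0.494 in prefrontal cortex), but their medians were 0.00337 ± 0.787 (SD of 7 genes), -0.493 ± 0.833 and -0.594 ± 0.999, so this does not account for the whole rise. A shift of resident cells away from the homeostatic state, or entry of cells from blood may underlie the pattern, and these were not separated.

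Of 395 groups of 5 libraries examined, 14 held 1 library far from the other 4, where chance gives about 1 in 20, or 19.8. In control white matter replicate 5, IDs without a symbol held 21% of counts (16.6 to 17.2 in the others). In TBI white matter replicate 3 they held 20.4% (17.2 to 18.1), and the 10 largest genes held 14.5% (9.97 to 10.7). The total of fWBI prefrontal cortex replicate 5 was 9.27 M counts (10.6 to 10.8). In log2 CPM, FCGR2A was 3.56 in fWBI white matter replicate 5 (6.15 to 6.81). In fWBI hippocampus, ENPEP was 1.95 in replicate 5 (1.21 to 1.38), NEUROD2 5.18 in replicate 5 (5.42 to 5.51) and CIITA 0.937 in replicate 4 (1.76 to 2.10). OLIG2 was 5.81 in control hippocampus replicate 3 (4.89 to 5.15) and NMD3 6.73 in TBI hippocampus replicate 4 (6.81 to 6.83). In prefrontal cortex, COL3A1 was 3.57 in control replicate 1 (4.41 to 4.67) and 5.15 in TBI replicate 5 (3.96 to 4.19), RNF112 was 6.20 in TBI replicate 5 (6.40 to 6.48) and ETV4 -0.49 in TBI replicate 2 (0.61 to 0.92).

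By the test of the difference itself, the fWBI effect differed between white matter and prefrontal cortex for 1654 genes and between white matter and hippocampus for 1488, and the TBI effect for 5 and 1. Against prefrontal cortex the differences of log2 fold changes after fWBI were -3.60 for MYT1, -3.84 for TNR, -3.27 for ASIC4, 5.72 for GPNMB, 5.85 for FCGR2A, 2.10 for VIM, 2.79 for LYZ, 1.58 for OLIG2, 1.17 for CFB and 3.07 for CCL2. Against hippocampus they were -3.92 for MYT1, -3.83 for TNR, -3.27 for CA10, 6.04 for FCGR2A, 2.09 for VIM, 2.40 for LYZ, 0.87 for OLIG2, 1.56 for CFB, 3.29 for CCL2, 2.98 for SERPINA3, 2.46 for MAMU-DMB, -1.80 for COL1A1 and -1.28 for COL3A1. After TBI, against prefrontal cortex, they were 1.67 for ADAMTSL2, 1.44 for DHRS4 and 1.03 for KCNMB4.

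Other splits of the same libraries into groups of the same sizes were counted, the real one included. In white matter, 1 of 100 splits gave as many genes for fWBI (2537, highest other 1026) and 1 of 100 for fWBI against TBI (1117, highest other 105), so chance can be excluded there. For TBI in white matter 1 of 100 gave as many (11, highest other 2), but the real count was 0 without control replicate 1 or 3. The splits do not separate TBI from these control libraries, so chance stays open for that count. Chance can also be excluded for fWBI against TBI in hippocampus (1 of 100, with 52 genes and highest other 0) and in prefrontal cortex (1 of 100, with 45 genes and highest other 0). For fWBI against control the share of splits was just under 0.05 in hippocampus (4 of 100, with 111 genes and highest other 2264) and in prefrontal cortex (3 of 100, with 179 genes and highest other 1692). These shares were not adjusted for the number of comparisons, and other splits called more genes, so chance stays open there. The splits with 2264 and 1692 genes, which put fWBI replicates 1 and 3 together with control replicates 3, 4 and 5, and fWBI replicates 1, 3 and 5 with control replicates 1 and 3, called far more genes than the real groups and point to a structure of the samples that the groups do not explain. Chance can be excluded for the total of 89 called list tests (1 of 100 regroupings of the 15 animals, highest other 8). This total does not settle each list test, and camera with an estimated correlation, which compares a list with other genes, called 31. For genes shared by fWBI and TBI in white matter, 1 of 100 regroupings gave as many (8; highest other 0), but regrouping removes both effects and does not test sharing given common controls. The shared number was 0 without control replicate 1 or 3 and as the median with split controls, and 19 without replicate 2, so sharing stays open. For differences between regions, 41 splits were drawn. For fWBI no other split reached the real count in white matter against prefrontal cortex (1 of 41, with 1654 genes and highest other 669). The same held against hippocampus (1 of 41, with 1488 genes and highest other 1059). A share of 1 of 41 is under 0.05 but is the smallest that 41 splits can give. It was not adjusted for the number of comparisons, so these splits alone do not exclude chance. Chance cannot be excluded for TBI in white matter against prefrontal cortex (3 of 41, with 5 genes and highest other 7). Nor can it be excluded against hippocampus (5 of 41, with 1 gene and highest other 518). Where edgeR called 0 genes every split is as large, so the splits say nothing about chance: TBI against control in hippocampus (100 of 100; highest other 1) and prefrontal cortex (100 of 100; highest other 1), shared genes in hippocampus (100 of 100; highest other 140) and prefrontal cortex (100 of 100; highest other 0), and hippocampus against prefrontal cortex for fWBI (41 of 41; highest other 0) and TBI (41 of 41; highest other 0). For the control regions the 16 exchanges are too few for a share under 0.05: 1 of 16 gave as many for white matter against prefrontal cortex (9381; highest other 5516), hippocampus against prefrontal cortex (2306; highest other 1) and white matter against hippocampus (8616; highest other 0).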

How the results depend on the processing

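The results without 2 control white matter libraries and without 3 animals were added after the data were seen; the other alternatives were planned. Of 336 alternative counts of genes, 223 were within 1.5 times the reported count and 113 moved further, 65 of these on leaving out 1 animal. Of 6211 alternative values of 357 named gene results, 5467 kept their direction and their side of the threshold, 661 were no longer called, 64 were newly called, 0 called values reversed and 19 uncalled values changed sign. Except where fewer genes or libraries were fitted, the cause was not tested.

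For fWBI against control in white matter (2537) the count was 1639 with only 2 groups fitted, 1604 with a log2 fold minimum of 1, 4062 with all 45 libraries and 1674 without the 2 control libraries; leaving out 1 animal gave 1747 to 3038. In hippocampus (111) it was 271 with DESeq2 and 72 with only 2 groups, and leaving out 1 animal gave 70 to 264. In prefrontal cortex (179) it was 442 with DESeq2, 387 with limma-voom, 110 with the fold minimum and 66 without 3 animals, and 73 to 218 on leaving out 1 animal. For TBI against control in white matter (11) it was 783 with DESeq2, 2 with limma-voom, 1738 with all 45 libraries, and 0 with only 2 groups, with the composition covariate, without 3 animals and without the 2 control libraries; leaving out 1 animal gave 0 to 25. In hippocampus (0) DESeq2 gave 59, and limma-voom and no filter 1 each, with 0 to 3 on leaving out 1 animal. In prefrontal cortex (0) DESeq2 gave 241, limma-voom 162, no filter 1, the covariate 12 and all 45 libraries 11, with 0 to 23 on leaving out 1 animal. For fWBI against TBI DESeq2 gave 138 in hippocampus (52) and 96 in prefrontal cortex (45); leaving out 1 animal gave 743 to 1170 in white matter (1117), 33 to 56 in hippocampus and 28 to 52 in prefrontal cortex.

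Between control regions, leaving out 1 animal gave 7881 to 10276 genes for white matter against prefrontal cortex, 1261 to 2356 for hippocampus against prefrontal cortex and 6751 to 9496 for white matter against hippocampus. For the difference of the fWBI effect, leaving out 1 animal gave 1014 to 2145 against prefrontal cortex and 837 to 1986 against hippocampus, and the 2 control libraries left out gave 1055 and 925; hippocampus against prefrontal cortex gave 0 in each setting. For TBI in white matter against prefrontal cortex (5) the count was 3 with DESeq2's size factors, with no filter and with no animal block, 1 without the 2 control libraries, 0 without 3 animals and 0 to 90 on leaving out 1 animal; against hippocampus (1) it was 0 with no filter, without the 2 control libraries and without 3 animals, and 0 to 200 on leaving out 1 animal.

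Genes shared by fWBI and TBI numbered 19 in white matter and 31 in prefrontal cortex at an adjusted p under 0.1; in white matter they numbered 0 with split controls and without the 2 control libraries. Leaving out 1 control library gave 0 to 19 in white matter, 0 to 1 in hippocampus and 0 to 17 in prefrontal cortex. Of 288 list tests (89 called) camera called 141 with a preset correlation, 81 of them shared with fry, and 31 with an estimated correlation; leaving out 1 animal gave 81 to 104.

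Animal numbers are shared between the irradiation groups but name different animals. Libraries with the same number in different groups had a median r of 0.015, with 15 of 45 pairs above 0.1, against 42 of 180 pairs with different numbers. Each library was also compared with the 5 libraries of its region in each other irradiation group, 90 comparisons in all. In 19 of them it correlated best with its own number, so these values do not show pairing by number. With this number as a replicate block, fWBI against control gave 1975 genes in white matter, 71 in hippocampus and 321 in prefrontal cortex, TBI against control gave 0 in white matter and 81 in prefrontal cortex, and fWBI against TBI gave 34 in hippocampus. Without the animal block the control comparison of white matter and prefrontal cortex gave 9027 genes.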

Other observations

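The gene groups here were fixed in advance; the genes that followed single animals and the blood cell genes were chosen only after the result was seen. In white matter after fWBI, ependymal genes were higher: FOXJ1, a transcription factor of ciliated cells, rose by 2.82 ± 0.32 (edgeR adjusted p = 2.63e-05), and 3 of 6 choroid plexus and ependyma genes rose, 5 adjusted over the list alone (median 1.46; fry adjusted p = 0.00218; adjusted p = 0.141 with an estimated correlation). Of 11 oxidative stress (NRF2) genes 5 rose, 6 adjusted over the list alone, among them FTL, the ferritin light chain (1.09 ± 0.16, edgeR adjusted p = 0.000217). Their median was 0.53 (fry adjusted p = 0.00386, adjusted p = 0.187 with an estimated correlation). In controls their median was 0.767 higher in white matter than in prefrontal cortex. Any grey matter in control white matter replicates 1 and 3 was thus not separated from this rise. DCX, a microtubule protein of migrating neuroblasts, fell by 1.61 ± 0.18 (adjusted p = 1.9e-05), 1 of 4 of 10 neurogenesis and proliferation genes that were lower, with 1 higher, on both counts (median -0.27; fry adjusted p = 0.000253; adjusted p = 0.14 with an estimated correlation). Endothelial genes went both ways, 3 of 15 higher and 2 lower on both counts (median 0.11; fry adjusted p = 0.455 for 1 direction and 1.7e-05 for either), and PECAM1, an endothelial adhesion molecule, rose by 1.55 ± 0.17 (adjusted p = 1.9e-05). In hippocampus PECAM1 rose by 0.73 ± 0.13 (adjusted p = 0.01), and without control animal 5 and fWBI animals 1 and 4 its adjusted p was 0.0866.

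CD3E averaged at most 1.06 CPM in any group, the value of control hippocampus. In white matter it averaged 0.761 ± 0.477 CPM after fWBI and 0.165 ± 0.13 in controls (SD), while CD8A averaged 6.54 ± 5.89 and 8.21 ± 3.74. In white matter GZMB, a cytotoxic granule protease, averaged 1.38 ± 1.1 CPM after fWBI and 0.0917 ± 0.0995 in controls (SD, n = 5), and CD4, which macrophages also express, 114 ± 20.4 and 31.4 ± 29.6. HBA averaged 26.3 ± 53.1 CPM in TBI white matter, and its log2 fold change of -4.98 ± 1.29 between fWBI and TBI (adjusted p = 0.027) was -1.74 without TBI animal 4 (adjusted p = 0.184).

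Of 10948 genes with a symbol, 3 followed the animal in all 3 regions, with r above 0.9 between every pair of regions and an SD above 1 on the log2 scale. ARL6IP1 averaged 1.36 to 2.40 CPM in 8 animals and 16.7 to 128 in the others. NDUFA1 averaged 0.748 to 1.48 CPM in TBI animals 2 and 3 and fWBI animals 2 and 3, against 25.9 to 75.1. LDHB averaged 3.16 to 4.14 CPM in control animals 1 and 3, against 23.6 to 56.7.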
